A study of Homo sapiens with 8 samples.

How the data were processed

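RNA from U87MG cells was labelled with biotin and hybridized to Illumina bead arrays, named in the labels' protocols as a Sentrix HumanRef-8 chip. The deposited table holds intensity values for 49424 probes on 8 arrays. This is more than a chip of that name is thought to carry, so the chip type is unsettled here, and any control probes among the rows were tested and counted in the adjustment with the rest. Per the submitters' processing notes the authors used lumi, an R package for Illumina arrays, and its version and settings are not given in the sources used here. Background correction, transformation and normalization are likewise not given. The deposited intensity values are on a linear scale, with no value below 42 and near-equal array medians, and the distributions of the 8 arrays as deposited are not identical. With the lowest values well above 0, any background that remains in them makes fold changes of dim probes too small. No detection p-values were used here, so probes could not be sorted into detected and undetected ones.

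Rows are named by bare numbers from 10008 to 7650768, which the file does not pair with genes. Of these, 258 equal an NCBI gene ID by number, and this was not used, since the numbers are those of the array's probes. Control probes could not be told apart. For the same reason 3 parts of the plan fixed before the data were examined could not be carried out. The 29 gene lists (579 entries) were not tested, the panel of aryl hydrocarbon receptor genes was not read out, and probes were tested singly in place of 1 probe per gene.

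Groups, times and replicate numbers were taken from the sample names. A second label numbers both untreated arrays of a time 1 and both treated arrays 2, and was not used. The replicate numbers of the names were tested as a block among the alternatives. All columns of values in the table were used. Intensities were converted to log2 with no added constant, and the values were otherwise kept as deposited. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend) to all 8 arrays with 1 mean per group, so that the 4 groups shared 1 estimate of the spread. Contrasts gave the kynurenine effect at 8 h and at 24 h, their difference, and the change of untreated cells from 8 h to 24 h. The average kynurenine effect came from an additive model of time plus treatment. P-values were two-sided and adjusted by Benjamini-Hochberg over all 49424 probes, with a threshold of 0.05. The residual degrees of freedom were 4, to which the prior added 15.4, and the median replicate SD of the brighter probes (the 24712 with a mean at or above the median) was 0.123 on the log2 scale.

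Probes to be named were set by rule before the data were examined. For the kynurenine effects it took the 10 largest rises and falls among those past the threshold whose 2 treated arrays both lay on 1 side of the 2 untreated ones. Where few passed, the rule also added probes by smallest unadjusted p, as values that did not pass. It further named probes for the average effect and for the difference between times. These additions were not made. Since the files do not pair the numbers with genes, only 2 rising and 2 falling probes are printed, chosen from those the rule gave after their values were seen. These are the largest rise at 8 h, the probe past the threshold at both times, and both falls at 24 h. For the time comparison, sizes are given without numbers.

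The fits were tested on simulated arrays with the real probes' means and variances drawn from the fitted prior, in which 50 probes each were changed by 1.5-, 2-, 3- and 4-fold. For the kynurenine effect at 8 h, 100% of the probes changed 2-fold and 58% of those changed 1.5-fold were recovered, with 14 false calls. For the average effect 96% of the 1.5-fold changes were recovered, with 9 false calls. The changed probes were taken from the 12356 brightest, so these shares do not apply to dim probes. The simulated variances did not depend on brightness. In the real data the 12356 brightest probes had a median replicate SD of 0.142 on the log2 scale, against 0.114 over all probes. The shares may therefore be too high for bright probes as well. They were obtained with as many changed probes as were simulated, and a shorter list sets a stricter threshold on the unadjusted p.

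Alternatives fixed before the data were examined were the brighter probes alone (by the mean over all arrays), quantile normalization, median centring, an intensity trend with robust priors, log2 of the value plus 16, only the 4 arrays compared, the replicate number within each time as a block, and each array left out in turn. Added later were the subtraction of each array's 5th percentile with a floor of 16, the mean of both effects in the fit of 4 groups, and the comparison of treated cells at 24 h against 8 h. The arrays' slide and scan date are not given in the sources used here, so no batch could be tested.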

Results

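Gene expression was profiled in U87MG, a human glioblastoma cell line, after exposure to kynurenine, a product of tryptophan breakdown. The parent study concerned kynurenine as a ligand of the aryl hydrocarbon receptor, a transcription factor that is activated by small molecules. Cells received 100 µM kynurenine or no treatment, and total RNA was taken after 8 h or 24 h. The 4 groups (untreated and kynurenine at each time) had 2 arrays each, 8 arrays in all. Each array gave a normalized intensity for 49424 probes. Probes are known here only by number, so the results below describe probes, not genes, and several probes can report on 1 gene. Median intensity per array lay between 79.3 and 80.1, and the brightest probe of an array between 24847 and 30562. Only 16.8% of the probes had a mean log2 intensity more than 1 above the median probe (2 times its level). The number of arrays limits the precision. The 24712 probes with a mean intensity at or above the median are termed the brighter probes. Their median probe had a 95% interval of ± 0.257 on the log2 scale, or 1.20-fold, for a difference of 2 arrays against 2. Nothing in the labels says whether the 2 arrays of a group came from separate cultures, so the tests measure the spread between these arrays, which may be technical.

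The arrays differed more between the time points than between treated and untreated cells. The slide of each array is not given in the sources used here, so a difference between slides cannot be told apart from one between time points. Across the brighter probes, the first principal component held 40.7% of the variance and parted all 24 h arrays from all 8 h arrays. The second component, with 11.9%, followed neither time nor treatment. The third held 10.8% and parted the 4 kynurenine arrays, with scores of 6.78 to 9.26, from the 4 untreated arrays, with scores of -11.7 to -5.56. In a two-sided exact permutation test of 4 arrays against 4, treatment on the third component gave p = 0.0286, the smallest this design allows, and an adjusted p of 0.2 over the 7 components tested. The same values held for time on the first component. Over the same probes, arrays of 1 group correlated at r = 0.990 to 0.992, treated and untreated arrays of 1 time at r = 0.989 to 0.991, and arrays of different times at r = 0.981 to 0.985. These correlations are across probes, which are not independent replicates.

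**Figure D1:**
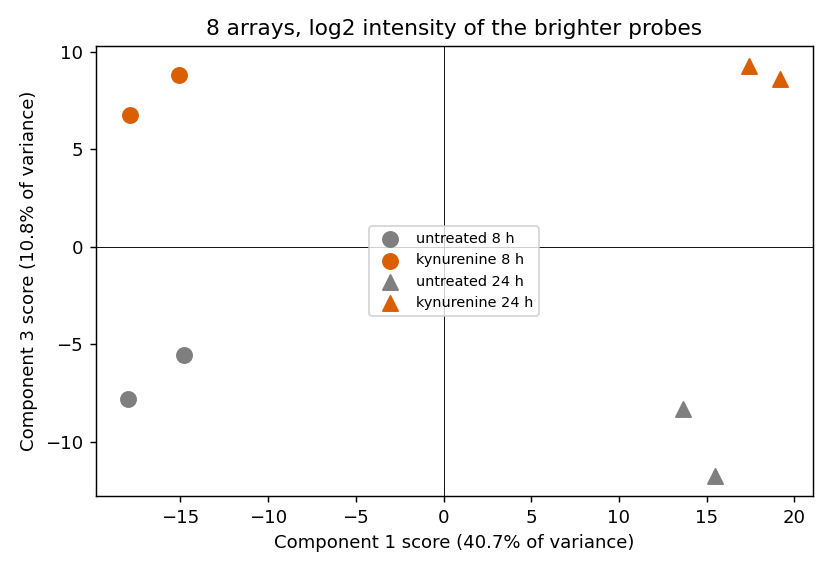
Scores of the 8 arrays on principal components 1 (x axis) and 3 (y axis) of log2 intensity, brighter probes, in log2 units. Circles are 8 h, triangles 24 h, gray untreated and orange kynurenine. The first component (40.7% of variance) parts the times and the third (10.8%) parts treated from untreated arrays.

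The first comparison asked which transcripts differ after 8 h of kynurenine. At that time 5 probes were higher and 0 were lower than in untreated cells at an adjusted p under 0.05 (limma, Benjamini-Hochberg over 49424 probes). Their rises lay between 0.80 and 1.25 on the log2 scale, with a median of 1.003, and 3 of the 5 exceeded 2-fold. The largest was probe 840685, which rose 2.38-fold, from an intensity of 186 ± 14.9 (SD, n = 2) to 448 ± 110 (SD, n = 2). Its log2 fold change was 1.25 ± 0.148 (SE), with an adjusted p of 0.00163. Probe 6760546 rose 1.74-fold, from 1256 ± 22.8 to 2182 ± 20.5 (SD, n = 2 each), with a log2 fold change of 0.80 ± 0.114 (SE) and an adjusted p of 0.0101. All 5 were bright, with a median mean intensity at the 97.6th percentile of all probes. At an unadjusted threshold of 0.05, 2791 probes passed, or 5.65% of those tested, where no change at all would give about 5%. Without kynurenine 8 h replicate 1 the count was 2, and without untreated 8 h replicate 1 it was 8, while without untreated 8 h replicate 2 or kynurenine 8 h replicate 2 it stayed 5, and these fits called 2, 3, 3 and 3 of the original 5. Probe 6760546 missed the threshold in all 4 of these fits (adjusted p of 0.0781 to 0.118 by limma), with a log2 fold change of 0.78 to 0.82, and 840685 missed it without kynurenine 8 h replicate 1 (0.996, adjusted p of 0.0619). An intensity trend with robust priors gave 8 probes, all higher, and background subtraction gave 55 (27 higher, 28 lower), none of them among the original 5. With background subtracted the original 5 had log2 fold changes of 0.83 to 1.63, with adjusted p of 0.0913 to 0.39 by limma. Their median SE went from 0.128 to 0.144, but the prior degrees of freedom fell from 15.4 to 0.424. This raises p at a given SE, so the lost calls do not show smaller changes.

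After 24 h of kynurenine, 1 probe was higher and 2 were lower than in untreated cells of that time at the same threshold. The probe that rose was again 6760546, from 1320 ± 54.7 to 2593 ± 213 (SD, n = 2 each), a 1.96-fold difference. Its log2 fold change was 0.97 ± 0.114 (SE), with an adjusted p of 0.00264 by limma. Probe 520682 fell from 571 ± 3.33 to 297 ± 40.5 (SD, n = 2 each), a log2 fold change of -0.95 ± 0.130 (SE) with an adjusted p of 0.0139. Probe 2570019 fell from 206 ± 13.98 to 116 ± 0.113 (SD, n = 2 each), a log2 fold change of -0.83 ± 0.124 (SE) with an adjusted p of 0.0358. An unadjusted 0.05 was passed by 2969 probes, or 6.01%. With 1 array fewer the folds changed little while the calls changed. The log2 fold change stayed between 0.89 and 1.06 for 6760546, between -1.09 and -0.81 for 520682 and between -0.90 and -0.76 for 2570019. The count was 1 (lower) without untreated 24 h replicate 1, 0 without untreated 24 h replicate 2, 5 without kynurenine 24 h replicate 1 (5 higher, 0 lower) and 5 without kynurenine 24 h replicate 2 (4 higher, 1 lower), and these fits called 0, 0, 1 and 2 of the original 3. Probe 6760546 still passed without either kynurenine 24 h array (adjusted p of 0.0233 and 0.0464 by limma) and 520682 without kynurenine 24 h replicate 2 (0.0332). The call of 2570019 ended without any 1 of the 24 h arrays, and also under the brighter probes alone (0.0816), an intensity trend with robust priors (0.164) and an added constant of 16 (0.0873). Background subtraction gave 77 probes (43 higher, 34 lower), of which 1 was among the original 3, and moved 2570019 to a log2 fold change of -1.44 with an adjusted p of 0.214.

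**Figure D2:**
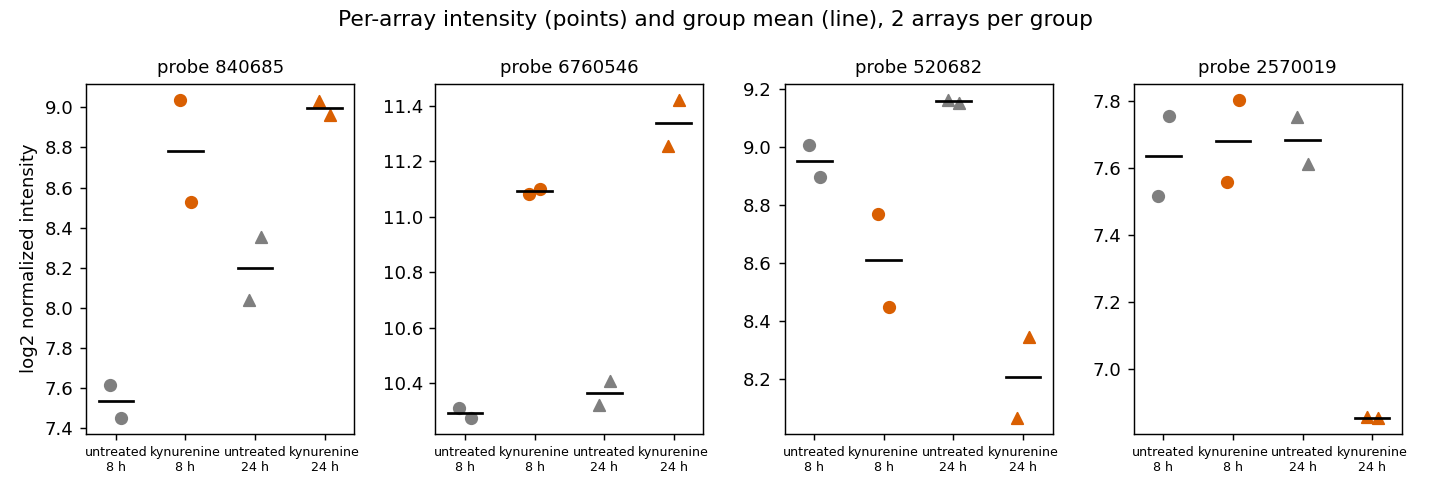
Log2 normalized intensity (y axis, a separate range per panel) of the 4 probes named for kynurenine, by group (x axis). Points are single arrays, 2 per group, and the line is their mean. Probe 6760546 was higher with kynurenine at both times, and probe 2570019 lay at 116 only in the 24 h kynurenine arrays.

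The probes called at 8 h were compared with their values at 24 h, which come from other arrays. All 5 had a log2 fold change above 0 at 24 h too, between 0.19 and 0.97 with a median of 0.72, but only 1 of them (6760546) passed the threshold there. The lowest was 0.19 ± 0.128 (SE), with an adjusted p of 0.918. Probe 840685 had a log2 fold change of 0.80 ± 0.148 (SE) at 24 h, with an adjusted p of 0.22. Of the 2 probes that fell at 24 h, 520682 had a log2 fold change of -0.34 ± 0.130 (SE) at 8 h and 2570019 one of 0.04 ± 0.124 (SE), and neither passed there (adjusted p of 0.789 and 0.994 by limma). The difference of the 2 effects was tested directly as an interaction. By limma 0 probes passed, with 2963 at an unadjusted 0.05, and a fit with an intensity trend and robust priors also gave 0 (2856 unadjusted). The largest such difference among the 4 named probes was -0.87 ± 0.176 (SE) for 2570019, with an adjusted p of 0.377. Without untreated 8 h replicate 2, 5 probes passed this test, and without untreated 24 h replicate 1, 1 probe, while background subtraction gave 101. Across all probes the effects at 8 h and 24 h were uncorrelated, with Pearson's r = -0.001 and Spearman's rho = -0.006 across probes. Wrongly grouping the arrays within each time gave values of r up to 0.0441 in size.

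**Figure D3:**
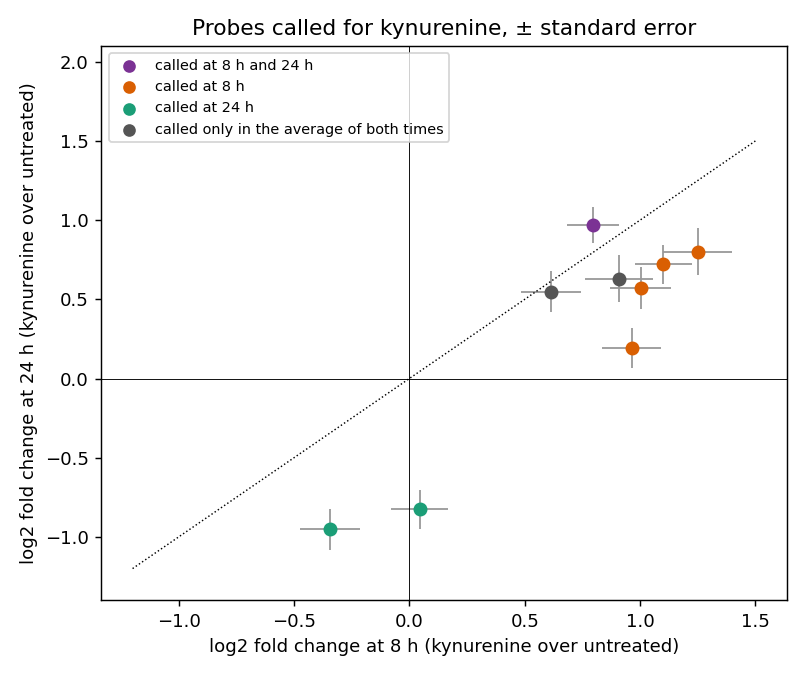
Log2 fold change of kynurenine over untreated at 8 h (x axis) and 24 h (y axis) for the 9 probes called at either time or in the average of both. Bars are standard errors from the limma fit, and the dotted line marks equal effects. The 5 probes called at 8 h lie at 0.19 to 0.97 on the 24 h axis.

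Averaged over both times, with 4 treated against 4 untreated arrays and time as a covariate, 6 probes were higher and 0 lower. Their log2 fold changes lay between 0.58 and 1.02. The highest was probe 840685 at 1.02 ± 0.116 (SE), with an adjusted p of 0.000722, and the smallest adjusted p was that of 6760546, at 6.64e-05 with a log2 fold change of 0.88 ± 0.0802 (SE). Of the 5 probes called at 8 h, 4 were among these 6, and 2 of the 6 were called at neither time alone. Probe 520682 had a log2 fold change of -0.65 ± 0.114 (SE) and missed the threshold (adjusted p of 0.0842 by limma). The count was 14 without untreated 8 h replicate 1 and 3 without untreated 8 h replicate 2. Averaging both effects in the fit of 4 groups, an alternative chosen after the data were seen, called 15 probes, 11 higher and 4 lower, which included all 6, and background subtraction left 0.

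Untreated cells differed far more between the times than treated from untreated cells did at either. Between 8 h and 24 h without treatment, 551 probes rose and 573 fell, 1124 in all, with 36 up and 45 down by at least 2-fold. The median size was 0.61 on the log2 scale. The largest rise was 5.87-fold, from 581 ± 84.9 to 3453 ± 936 (SD, n = 2 each), and 4 probes rose by over 4-fold. The largest fall had a log2 fold change of -1.60 ± 0.124 (SE), from 1076 ± 147 to 354 ± 15.2 (SD, n = 2 each). Without untreated 8 h replicate 1 the count was 655, without its replicate 2 it was 678, without untreated 24 h replicate 1 it was 468, and without its replicate 2 it was 555. An intensity trend with robust priors gave 748 probes and background subtraction 161.

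The same comparison in kynurenine-treated cells, added after the data were seen, called 1515 probes, 616 higher and 899 lower at 24 h. These arrays are separate from the untreated ones. Of the calls, 225 higher and 341 lower probes were shared with the untreated comparison, against 6.87 and 10.4 for independent lists of these sizes. That expectation spreads calls evenly over all probes, while the calls lay mostly among bright ones (median percentiles of 90.4 untreated and 89.2 treated). Both comparisons also use the same estimate of each probe's spread, so part of the excess may come from these 2 features. The time effects of the 2 comparisons correlated at r = 0.458 (Spearman's rho = 0.233) across all probes and at r = 0.578 (rho = 0.404) across the brighter probes. Whether the time effect differed with kynurenine is the interaction tested above, with 0 probes past the threshold by limma. The count in treated cells fell to 636 without kynurenine 8 h replicate 2, 683 without kynurenine 24 h replicate 2, 826 without kynurenine 8 h replicate 1 and 992 without kynurenine 24 h replicate 1, and to 166 with background subtracted.

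**Figure D4:**
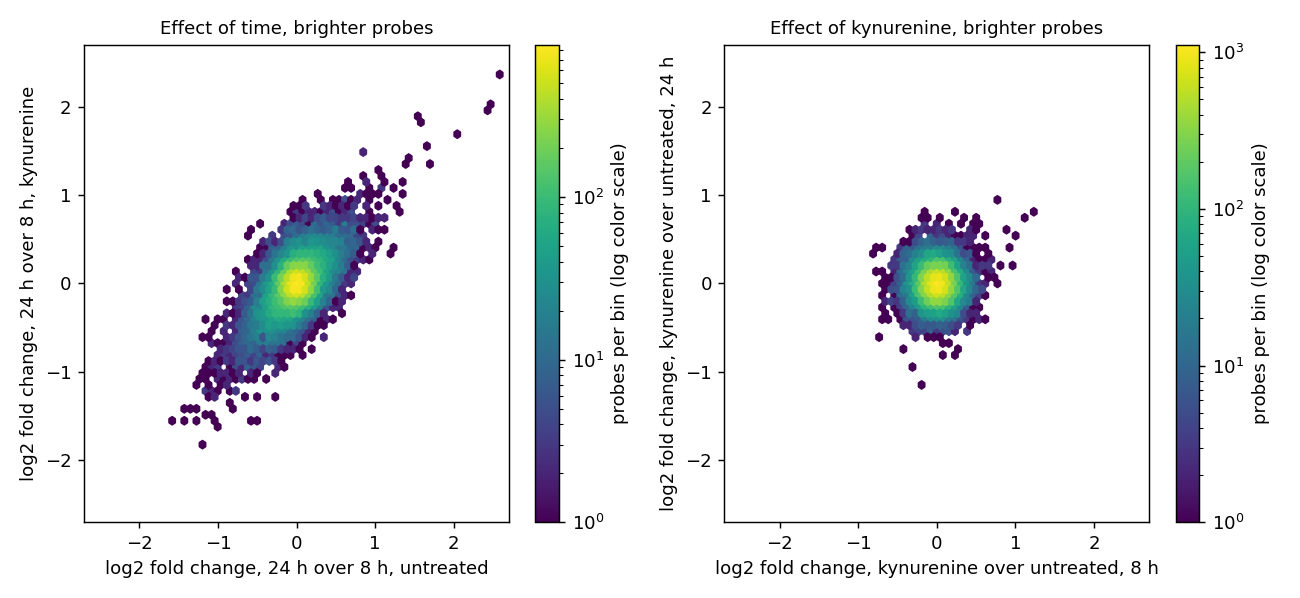
Log2 fold changes of the brighter probes, with color giving the number of probes per bin on a log scale. On the left the 24 h over 8 h change in untreated (x axis) and treated (y axis) arrays lies along the diagonal (r = 0.578). On the right the kynurenine effects at 8 h (x axis) and 24 h (y axis) form a round cloud (r = 0.004) with a few probes high on both.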

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

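Background subtraction, the mean of both effects and the comparison of treated cells over time were chosen after the data were seen. Under the brighter probes alone, quantile normalization, median centring and the added constant of 16, each count stayed within 1.5 times its value as reported, as did those for kynurenine at 8 h and 24 h and for both time comparisons in fits of only the 4 arrays compared. An intensity trend with robust priors gave 8 probes at 8 h and 748 for untreated cells over time. The mean of both effects in the fit of 4 groups gave 15 for the average effect. Subtracting background gave 55 probes at 8 h, 77 at 24 h, 101 for their difference, 161 and 166 for time in untreated and treated cells, and 0 for the average effect. Most of the added kynurenine calls lay at the floor, with 2 or more arrays at 16 for 125 of 132. Subtraction also lowered the prior degrees of freedom of the fit of 4 groups from 15.4 to 0.424. A call lost in that fit therefore does not by itself show a smaller change. Same-numbered arrays did not deviate together (r = -0.011 at both 8 h and 24 h, all probes), so no pairing was seen. A weak effect shared by same-numbered arrays could be missed by this value. With the replicate block the counts were 20 at 8 h (13 higher, 7 lower, all 5 original probes included), 3 at 24 h, 10 for the average effect, 0 for the difference, and 629 and 724 for time in untreated and treated cells. Leaving out 1 array gave 2 to 8 probes at 8 h, 0 to 5 at 24 h, 0 to 5 for their difference, 3 to 14 for the average effect, and 468 to 1137 and 636 to 1541 for time in untreated and treated cells. The cause of these changes was not tested beyond the fewer arrays compared. The correlation of the effects at 8 h and 24 h stayed between -0.034 and 0.033. For the probes called for kynurenine and the 2 largest changes each way over time, 0 of 192 values under the alternatives changed sign and 30 no longer passed. The signs say little, since these probes were chosen for arrays that do not overlap between the groups compared. Leaving out 1 array could therefore not turn a sign, and several alternatives leave the fold change itself as it was. Of 16 alternatives each, 2 ended the call of probe 840685 at 8 h, 5 and 2 those of 6760546 at 8 h and 24 h, 4 that of 520682 and 8 that of 2570019. The gene lists (camera with an estimated correlation included) and other probes of the same gene were not run for want of gene names.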

Other observations

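Chosen after the result was seen were the tests of the 8 h probes at 24 h, of too few arrays and of a slide or batch, the restriction to splits balanced over time, the difference of same-side and opposite-side shares, and the counts for other splits within each time. Background subtraction was added after the data were seen. Probe 840685 also rose in untreated cells from 8 h to 24 h, by 0.66 ± 0.148 (SE) on the log2 scale with an adjusted p of 0.0185 by limma. Its intensity in untreated cells went from 186 ± 14.9 to 295 ± 44.7, and in kynurenine-treated cells it was 448 ± 110 at 8 h and 511 ± 17.4 at 24 h (SD, n = 2 each). Probe 6760546 had a log2 change of 0.07 ± 0.114 (SE) in untreated cells over the same interval, with an adjusted p of 0.937. The other probes called at 8 h changed there by 1.03 ± 0.123, 0.59 ± 0.133 and -0.05 ± 0.128 (SE). Their adjusted p were 7.89e-05, 0.0206 and 0.966 by limma, where 1124 of all 49424 probes passed. These changes and the kynurenine effects at 8 h share the untreated 8 h arrays, so low values there would raise both. Probe 2570019 lay at 199 ± 23.0, 206 ± 24.8 and 206 ± 13.98 in untreated 8 h, kynurenine 8 h and untreated 24 h cells, and at 116 ± 0.113 in kynurenine 24 h cells (SD, n = 2 each). The average effect called 6 probes, and the highest of the other splits of the arrays into 4 and 4 with as many arrays of each time on both sides called 0. There are 18 such splits with the real one, too few for a share under 0.05. The planned count was over all 34 estimable splits, of which only the real one called 6 and the highest other called 1. It was narrowed after the result was seen, since the sides of the other 16 splits partly follow the time point and such splits have less power.

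The 5 probes called at 8 h had a median log2 fold change of 0.72 at 24 h, on other arrays, though only 1 of them passed the threshold there. This median exceeded that of 100% of 10000 random sets of 5 probes of matched brightness, the highest of which reached 0.30. The median brightness of the 5 probes, at the 97.6th percentile, decides little about variation near background. Background left in the values may shrink changes of dim probes, and each comparison with calls had a median percentile between 89.2 and 97.6. Probe 840685 lay at the 90.0th, with an intensity of 186 ± 14.9 (SD, n = 2) in untreated cells at 8 h. The median change of -0.00569 over the brighter probes at 24 h decides nothing about a shift of whole arrays, since the deposited values have near-equal array medians. These values suggest, as a hypothesis, a response to kynurenine at both times in most of this set, with 1 probe against it, at 0.19 ± 0.128 (SE) at 24 h (adjusted p of 0.918 by limma) and a difference between the times of -0.77 (adjusted p of 0.445). Handling that differed between treated and untreated cultures at both times was not tested and stays open, and some of the 5 probes may report on 1 gene.

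Kynurenine called 5 and 3 probes where 24 h against 8 h in untreated cells called 1124 with as many arrays. Comparisons of 2 arrays against 2 can thus pass the threshold on this chip. The time comparison had more and larger changes, up to 5.87-fold, so it cannot tell whether more arrays would call smaller kynurenine changes. Changes close to 2-fold could still be missed with lists this short, as 1 probe with a log2 fold change of 0.91 ± 0.148 (SE) at 8 h had an adjusted p of 0.052. Compression of fold changes by background left in the values cannot be told apart from a small response, since subtraction gave 132 calls, but 125 of these had 2 or more arrays at the floor. In the fit of all probes, subtraction moved the median log2 fold change of the 5 probes from 1.003 to 1.05. Their median SE went from 0.128 to 0.144, and the prior degrees of freedom fell from 15.4 to 0.424, which weakens the tests. Among the 12356 brightest probes fitted alone, where 0.176% of values met the floor, subtraction left 0 calls by limma at either time. There the prior degrees of freedom fell from 15.9 to 4.31, so these lost calls do not by themselves show smaller changes.

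Principal component 3 parted treated from untreated arrays, with an adjusted p of 0.2 over 7 components by exact permutation, so this may be chance. If it is not, a candidate explanation is small changes in many probes in one direction at both times. Of the brighter probes, 6.35% had treated arrays on the same side of the untreated ones at both times and 6.14% on opposite sides, a difference of 0.21 points. The criterion set before, that the same-side share of the real grouping be the highest of the 9 combinations of splits within each time, was met, as the others reached 6.03% on the same side and 6.30% on either side. But 9 combinations are too few for a share under 0.05, and the difference of both shares reached 1.05 points in size in the others. With only the 4 arrays of a time, 2760 probes passed an unadjusted 0.05 at 8 h against 2164 and 2342 in the other two splits, and 2939 at 24 h against 2084 and 2222. The average effect had 2690 such probes, and other splits reached 2860. Across the brighter probes the effects at 8 h and 24 h had r = 0.004 (Spearman's rho = -0.005) and equal signs in 49.9%. These values show no shared direction. The other combinations gave r of up to 0.0649 in size, so a weak shared direction could be missed and the explanation stays open.

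The time effects of untreated and treated arrays correlated at r = 0.458 across all probes, and time in culture and a slide or batch that follows the time point cannot be told apart, since the slides are not given in the sources used here.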
